A study of Mus musculus with 56 samples.

How the data were processed

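Total RNA of 56 mouse mammary tumors was measured on Affymetrix 3' expression arrays, with 100 ng of RNA labelled per array, per the labels' protocols. The deposited values are log2 expression per probe set, made by the authors with RMA (background correction, quantile normalization and summary of the probes), per the submitters' processing notes; the version is not given in the sources used here. The value distributions showed 2 sets: array medians of 5.92 to 6.00 for wild-type hosts and 5.57 to 5.71 for Tgfb1 heterozygote hosts, so the 2 host genotypes were treated as normalized separately. Comparisons of irradiated with sham-irradiated hosts lie within a set. Those between host genotypes lie across sets, where the planned test does not separate genotype from normalization; their counts are given with that limit and with all arrays quantile normalized together.

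Groups came from the sample labels alone. Each array is labelled as a separate tumor; the labels do not say whether tumors shared a host, and p-values measure the spread between these samples. Labels give no batch, date or radiation dose. Replicate numbers do not recur across groups. No columns were identical, and the highest correlation between 2 arrays was 0.980. Signal above background per array was not analysed here, since values per probe were not used.

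Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 were unnamed here; only the first kind was used. Symbols were updated through gene identifiers of the GRCm38.p6 annotation, which matched 12467 of the 12508 genes tested and also gave the chromosomes. A probe set was kept if it exceeded the median of all values on at least 6 arrays, and the probe set with the highest mean stood for its gene. Dimmer probe sets of Tgfb1 and Esr1, with group means below that median of 5.83, were not used in the tests. The level of the gene lost in the transplants is not reported here.

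limma 3.58.1 in R 4.3.3 was fitted to all 56 arrays with 4 group means (lmFit and eBayes), with 7 contrasts and a Benjamini-Hochberg adjusted p threshold of 0.05. Contrasts were host irradiation in each host genotype, their difference and mean, and host genotype in each irradiation group and their mean. Named genes were, per contrast and direction, the 10 with the lowest p among those called, or the 3 with the lowest p where none was called, of which the text gives a part, plus Tgfb1 and Esr1. For gene lists they were 2 to 4 members with the lowest p. The rule and 30 gene lists, with 566 genes of which 455 were measured, were fixed before the data were examined; genes named from chromosome 13 other than Ankra2, Adamts16 and Mterf3 were chosen after. Lists were tested with fry, which asks whether genes of a list move one way on balance, and with camera at a preset correlation of 0.01 and an estimated one. With the estimated correlation no list of more than 1 gene was called. A list score is the mean log2 value of its genes, with 95% bootstrap intervals from 10000 draws. Single values were compared by exact permutation tests, and values averaged over host genotypes by 100000 permutations within genotype.

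The methods were tested on simulated data made from the real residuals, reassigned at random within host genotype, with 200 of 12508 genes, and the proliferation list besides, changed by known folds in 10 simulations. In wild-type hosts limma recovered 53.5% of genes changed 1.5-fold, 79.7% of those changed 2-fold and 97.2% of those changed 4-fold; 11.2% of its calls were false. In heterozygote hosts it recovered 37.9%, 69.3% and 95.4%, with 3.85% of calls false. For irradiation averaged over host genotypes it recovered 65.5%, 88.0% and 98.7%, with 5.47% false. The proliferation list, changed 2-fold, was called by fry in 10 of 10 simulations of each of these comparisons, and 5, 4 and 5 unchanged lists were called in all.

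Alternatives were no filter, a stricter filter, all probe sets, quantile normalization, a trended and robust eBayes, array weights, the 3' minus 5' difference or the first spike-in component as a covariate, only the 2 groups compared, and each array left out in turn. After the data were seen, the 18S control as a covariate, leaving out arrays with a mean 18S value below 11, the low 18S arrays of wild-type hosts alone, and list tests and named genes without each array in turn were added. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.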

Results

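The series measured gene expression in 56 mammary tumors that grew from p53-null mammary fragments, which lack a tumor suppressor of the DNA damage response. The fragments themselves were not irradiated. They were placed in mammary fat pads of female BALB/c mice whose own epithelium had been removed at 3 weeks of age, and the host mouse had been irradiated or sham-irradiated 3 days before. Hosts were wild type or heterozygous for Tgfb1, the gene of the cytokine transforming growth factor beta 1. There were 9 tumors from sham-irradiated wild-type hosts, 23 from irradiated wild-type hosts, 6 from sham-irradiated heterozygote hosts and 18 from irradiated heterozygote hosts. The design asks whether irradiating the host, and the host's Tgfb1 genotype, changed the expression profile of the tumor that arose. Each tumor had 1 array, and the number of arrays limits the precision.

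Tumors differed widely in the level of epithelial genes within every group. Bulk RNA does not tell whether this reflects cell makeup or the state of the tumor cells. The epithelial junction list, which holds genes such as Cdh1 and Epcam that join epithelial cells, had scores from 5.47 to 10.22 (log2, n = 23) among tumors of irradiated wild-type hosts. In sham-irradiated wild-type hosts the scores ran from 5.76 to 10.14 (n = 9). The first principal component held 29.3% of the variance in the 32 tumors of wild-type hosts and 23.8% in the 24 tumors of heterozygote hosts. Its mean did not differ detectably between irradiated and sham hosts (exact permutation test, two-sided, p = 0.831 in wild-type and p = 0.448 in heterozygote hosts).

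Control probe sets also differed between groups. The 18S ribosomal RNA control was 11.28 ± 1.78 (SD, n = 9) in sham-irradiated wild-type hosts and 12.74 ± 0.90 (SD, n = 23) in irradiated ones (exact permutation test, two-sided, p = 0.00444), with 4 and 2 arrays below 11. In heterozygote hosts it was 11.75 ± 1.01 (SD, n = 6) and 12.07 ± 0.71 (SD, n = 18, exact permutation p = 0.401). The low arrays of wild-type hosts were WT_sham replicates 60, 61, 64 and 65 and WT_irradiated replicates 57 and 59, the highest numbers of that genotype. Those of heterozygote hosts, Het_sham replicate 19 and Het_irradiated replicates 4 and 29, did not follow the numbering. Whether the numbers follow a batch is not given. The 3' minus 5' difference of the Actb and Gapdh controls, a sign of RNA integrity, was 0.405 ± 0.167 (SD, n = 6) in sham-irradiated and 0.273 ± 0.108 (SD, n = 18) in irradiated heterozygote hosts (exact permutation p = 0.0297). In wild-type hosts it was 0.214 ± 0.030 (SD, n = 9) and 0.215 ± 0.159 (SD, n = 23, exact permutation p = 0.994). WT_irradiated replicate 57, among the low 18S arrays, had the highest value of the series, 0.911.

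**Figure D1:**
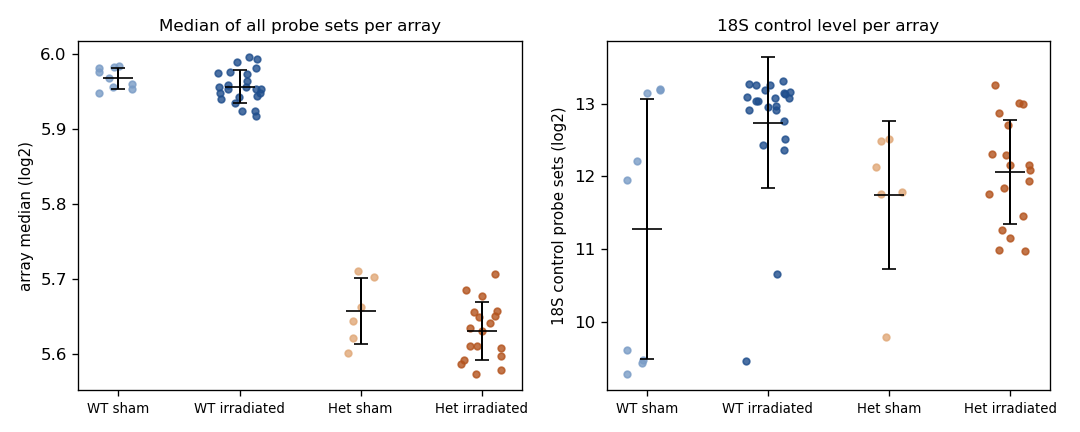
Each point is 1 array, placed by group; the left panel gives the array's median over all probe sets (log2) and the right panel its mean 18S control value (log2), with the group mean and SD in black. Medians run from 5.92 to 6.00 in wild-type hosts and from 5.57 to 5.71 in heterozygote hosts, with no overlap.

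In wild-type hosts, no gene passed the test between tumors of irradiated and sham-irradiated hosts. The lowest p-values among genes lower after host irradiation belonged to Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, to Ap2a2, an adaptor subunit of endocytosis, and to Zgpat. Hmox1 was at 9.18 ± 1.64 (SD, n = 9) in sham-irradiated and 7.66 ± 0.74 (SD, n = 23) in irradiated hosts, a log2 fold change of -1.52 with a standard error of 0.35 (limma adjusted p = 0.238), and 2 of 23 tumors of irradiated hosts lay above the sham median. Without WT_sham replicate 46 it was -1.06 (limma adjusted p = 0.392). Log2 fold changes were -0.44 for Ap2a2 and -0.42 for Zgpat. Among genes with higher values, Adamts16, a secreted metalloproteinase, had 0.33, Mterf3, a regulator of mitochondrial transcription, 0.39 and Sspo 0.30, with the same adjusted p of 0.238; 22, 23 and 21 of the 23 tumors of irradiated hosts lay above the sham median. Of 12508 genes, limma called 0, and 884 had an unadjusted p under 0.05. Tgfb1 was at 9.15 ± 0.92 (SD, n = 9) and 8.74 ± 0.41 (SD, n = 23; log2 fold change -0.41, limma adjusted p = 0.747), and without WT_sham replicate 46 the log2 fold change was -0.14. Esr1, the estrogen receptor gene, had a log2 fold change of 0.30 (limma adjusted p = 0.936), 0.15 without WT_irradiated replicate 59 and 0.19 without WT_sham replicate 3. The dimmer probe sets gave -0.11 for Tgfb1 and 0.07 and 0.17 for Esr1. With the 18S control as a covariate Mterf3 was at 0.25, and among the arrays of low 18S alone Ap2a2 was at -0.17 and Hmox1 at -0.94.

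Of the 30 gene lists, 1 passed in wild-type hosts: the erythrocyte list, of which 1 gene was measured, Alas2, an enzyme of heme synthesis in red cell precursors. Its log2 fold change was -1.66 with a standard error of 0.42 (fry adjusted p = 0.00778 over the lists, limma adjusted p = 0.238 over all genes). With 1 gene no correlation between genes can be estimated. Alas2 was at 7.37 ± 2.20 (SD, n = 9) in sham-irradiated hosts, where WT_sham replicate 46 had 12.68. Without that tumor the log2 fold change was -1.0 and the fry adjusted p 0.0637. None of the 23 tumors of irradiated hosts lay above the sham median. The list also lost its call without the filter and with either alternative for the 18S control, which was lower in the sham group. Other lists did not pass. The 4 measured mast cell genes, Cma1, Tpsb2, Tpsab1 and Mcpt2, all had negative log2 fold changes (median -0.72, fry adjusted p = 0.737), and 0 passed when adjusted over the list alone; without WT_sham replicate 46 the median was -0.32. Of 13 oxidative stress genes, 1, Hmox1, was lower when adjusted over the list alone (fry adjusted p = 0.737 for the list). Of 21 hypoxia and glycolysis genes 2 had positive log2 fold changes (median -0.22, fry adjusted p = 0.737); Aldoa, a glycolytic enzyme, was at -0.34 and Ero1a at -0.66.

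In Tgfb1 heterozygote hosts, likewise, no gene passed between irradiated and sham-irradiated hosts. Values were higher for Derl2, a component of protein export from the endoplasmic reticulum (log2 fold change 0.47, SE 0.12), G6pc3, a glucose-6-phosphatase (0.48, SE 0.12), and Ankra2 (0.45, SE 0.12). They were lower for Galnt6, which starts mucin-type glycosylation (-0.84, SE 0.20), for Ifnz, an interferon gene (-1.20, SE 0.30), and for 1110038F14Rik (-0.44, SE 0.12). All 6 had a limma adjusted p of 0.627. Of the 18 tumors of irradiated hosts, 17, 18 and 17 lay above the sham median for the first 3 genes and 1, 1 and 0 for the last 3. limma called 0 of 12508 genes, and 730 had an unadjusted p under 0.05. Tgfb1 was at 8.07 ± 0.98 (SD, n = 6) and 8.46 ± 0.46 (SD, n = 18; log2 fold change 0.39, limma adjusted p = 0.922), and without Het_sham replicate 52 the log2 fold change was 0.02. Without Het_sham replicate 58 that of Galnt6 was -0.44. Esr1 had a log2 fold change of 0.54 (limma adjusted p = 0.939). It was 0.10, 0.16 and 0.36 without Het_sham replicate 52, Het_sham replicate 58 and Het_irradiated replicate 32, and 0.85 and 0.84 without Het_sham replicates 19 and 38. The dimmer probe sets gave -0.06 for Tgfb1 and 0.0002 and 0.19 for Esr1.

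No gene list passed in heterozygote hosts by fry. The basal and myoepithelial list had a median of -0.54 over 17 genes (fry adjusted p = 0.478), and 1 gene was lower when adjusted over the list alone: Col17a1, a hemidesmosome collagen, at 7.87 ± 3.00 (SD, n = 6) in sham-irradiated and 5.09 ± 1.31 (SD, n = 18) in irradiated hosts. Krt5, a basal keratin, had a log2 fold change of -1.94. Without Het_sham replicate 19, which had a low 18S control, the list's median was -0.23, Krt5 was at -1.08 and Krt16 at -0.61. The keratinization score difference went from -0.66 to -0.18 without the same tumor and to -1.03 without Het_sham replicate 52 (fry adjusted p = 0.211). Krt5 was at -2.53 without Het_sham replicate 52 or 15, and lower in each case when adjusted over the list alone. All 9 keratinization genes had negative values (fry adjusted p = 0.432), and Krt16 was lower when adjusted over the list alone (-1.54). The immediate early list had a median of 0.32 over 19 genes (fry adjusted p = 0.432), with Ier2 at 0.53, Ier3 at 0.86 and Fos at 0.52. Of 7 neutrophil genes, Csf3r, the receptor of the granulocyte growth factor, was higher when adjusted over the list alone (0.94, fry adjusted p = 0.446 for the list). Of 17 p53 target genes, Gadd45a, a growth arrest gene, was higher on the same basis (1.18, fry adjusted p = 0.680 for the list). Without Het_sham replicate 52 the neutrophil median went from 0.77 to 0.49. These calls over a list alone each ended without single arrays: 3 of the 56 for Col17a1, 13 for Krt16, 11 for Csf3r and 4 for Gadd45a.

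**Figure D2:**
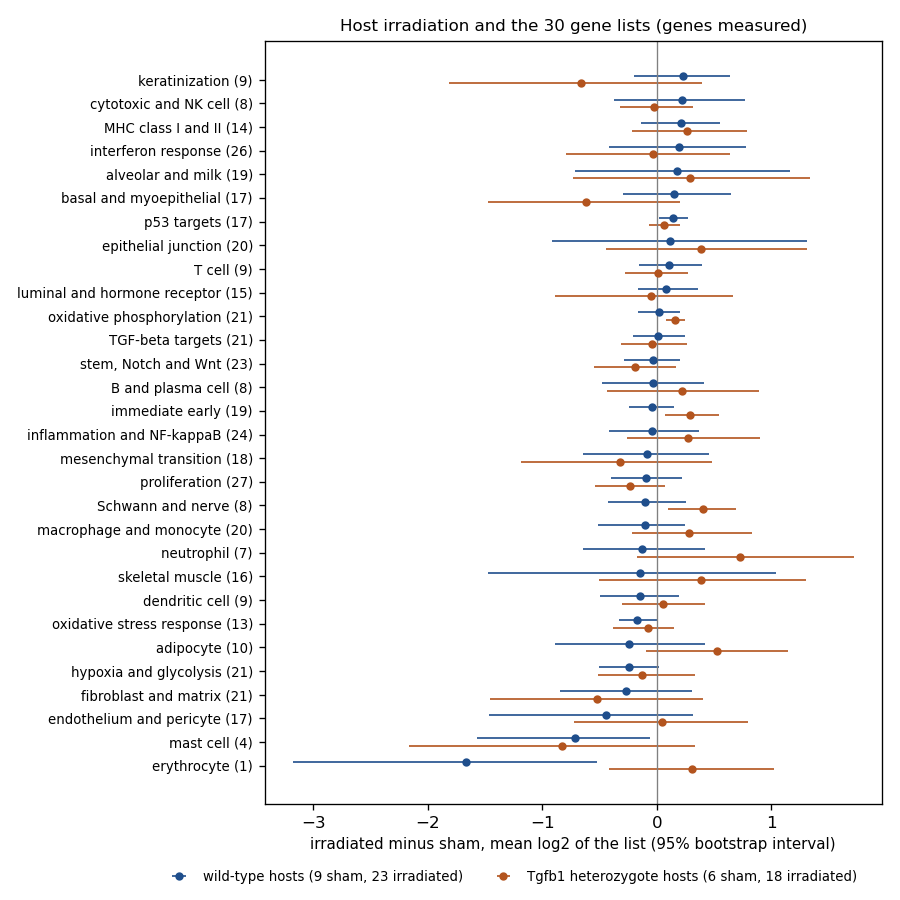
The difference of mean list score, irradiated minus sham (log2), for each of the 30 gene lists, with 95% bootstrap intervals and the number of measured genes in brackets; blue is wild-type and orange heterozygote hosts. Most intervals span 0. Those that do not are the p53 target, mast cell and erythrocyte lists in wild-type hosts. In heterozygote hosts they are the oxidative phosphorylation, immediate early, and Schwann and nerve lists. Of these only the erythrocyte list passed by fry. The mast cell list lies at -0.71 in wild-type hosts (-0.35 without WT_sham replicate 46). It lies at -0.82 in heterozygote hosts (-0.23 without Het_sham replicate 52), where its interval spans 0.

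The effect of host irradiation was then compared between host genotypes, and no gene passed the test of the difference. G6pc3 had the lowest p, with a difference of 0.68 on the log2 scale (SE 0.16, limma adjusted p = 0.894). Tmem101 was at 0.54 and Nadsyn1, an enzyme of NAD synthesis, at 0.90. Ikzf4, a lymphoid transcription factor, was at -0.77 (-0.50 with array weights), Ston2 at -1.48 and Clec2e at -0.55. Tgfb1 differed by 0.80 (SE 0.36, limma adjusted p = 0.999), by 0.53 without WT_sham replicate 46 and by 0.44 without Het_sham replicate 52. The dimmer Tgfb1 probe set gave 0.05. limma called 0 of 12508 genes, 605 had an unadjusted p under 0.05, and no gene list passed (fry adjusted p = 0.132 for the erythrocyte list, 0.478 for keratinization and for immediate early genes). Across the 12508 genes, which are not independent replicates, the irradiation effects in the 2 host genotypes had Pearson's r = 0.112 (permutation p = 0.614) and Spearman's rho = 0.116 (permutation p = 0.554). In 100 relabellings of the tumors, 95% of Pearson values lay between -0.397 and 0.318.

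Averaged over both host genotypes, Ankra2 rose in tumors of irradiated hosts. Ankra2, which encodes an ankyrin repeat protein, lies on chromosome 13 from 98263076 to 98274754 (GRCm38.p6). It went from 7.54 ± 0.20 (SD, n = 9) to 7.89 ± 0.27 (SD, n = 23) in wild-type hosts and from 6.97 ± 0.14 (SD, n = 6) to 7.42 ± 0.24 (SD, n = 18) in heterozygote hosts. The mean log2 fold change was 0.40 (SE 0.08, limma adjusted p = 0.0276), and 20 of 23 and 17 of 18 tumors of irradiated hosts lay above their sham median. It was the only one of 12508 genes that limma called; 972 had an unadjusted p under 0.05. Lower values that did not pass were those of 5430405H02Rik (-0.38), Gigyf1 (-0.33) and Top1mt (-0.43). Tgfb1 had a mean log2 fold change of -0.01 and Esr1 of 0.42 (limma adjusted p = 0.994 and 0.815). The Tgfb1 value was 0.12 without WT_sham replicate 46 and -0.19 without Het_sham replicate 52. The Esr1 value was 0.20 and 0.23 without Het_sham replicates 52 and 58, 0.14 with array weights and 0.83 with the 18S control as a covariate. The dimmer probe sets gave -0.09 for Tgfb1 and 0.04 and 0.18 for Esr1. The Ankra2 call ended with the 18S control as a covariate (0.31, limma adjusted p = 0.325) or the 3' minus 5' difference (0.36, limma adjusted p = 0.0607), and without the arrays of low 18S (0.38, limma adjusted p = 0.0543); over the other alternatives the adjusted p ran from 0.00784 to 0.0363. It also ended without WT_sham replicate 3, 60 or 64 or Het_sham replicate 19, 38 or 52, with limma adjusted p of 0.0589, 0.0781, 0.0853, 0.119, 0.055 and 0.0728.

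Genes of chromosome 13 had higher values as a group in tumors of irradiated hosts, a feature chosen after its values were seen. Of the 100 genes with the lowest p for irradiation averaged over host genotypes, 26 lie on chromosome 13, and all 26 had higher values; the chromosome holds 448 of the genes tested, or 3.58%. Rasa1, a negative regulator of Ras (0.48), Psma2, a proteasome subunit (0.31), and Cdk7, a kinase of transcription and the cell cycle (0.38), were among them. None of these 3 passed alone, though all 3 did with array weights and Rasa1 also with all probe sets. The score of the chromosome, the median of its genes minus that of all genes, was -0.08 ± 0.13 (SD, n = 9) in sham-irradiated and 0.04 ± 0.08 (SD, n = 23) in irradiated wild-type hosts (exact permutation test, two-sided, p = 0.00182). In heterozygote hosts it was -0.09 ± 0.11 (SD, n = 6) and 0.04 ± 0.13 (SD, n = 18; exact permutation p = 0.0308). Scores of irradiated-host tumors lay above the sham median in 23 of 23 and 17 of 18 cases. Among 20 chromosomes, with tumors permuted within host genotype, the family-wise p was 0.00793 and the adjusted p 0.005.

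**Figure D3:**
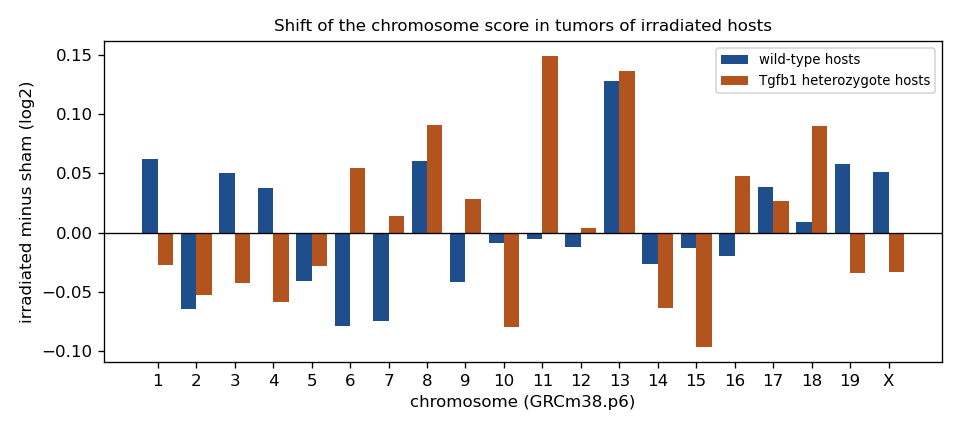
Difference of the chromosome score, irradiated minus sham (log2), for each chromosome, in wild-type (blue) and heterozygote (orange) hosts. Chromosome 13 is at 0.13 in wild-type and 0.14 in heterozygote hosts; chromosome 11 is at -0.01 and 0.15.

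**Figure D4:**
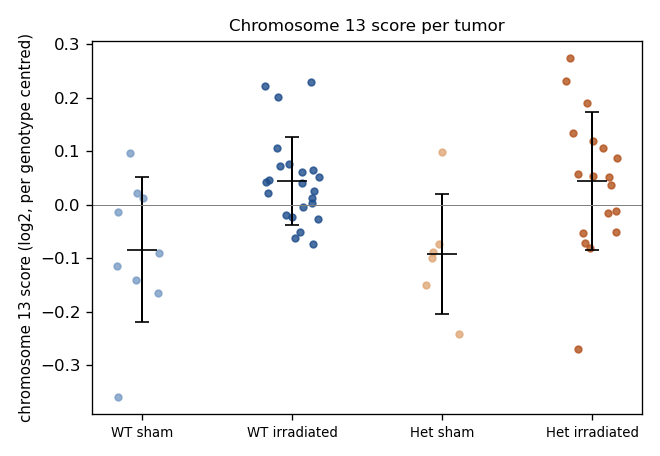
Chromosome 13 score of each tumor (log2, centred within host genotype), by group, with the group mean and SD in black. Both irradiated groups have a mean of 0.04, and the sham groups have means of -0.08 and -0.09.

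Among gene lists, none passed for irradiation averaged over host genotypes. The 4 mast cell genes, which encode mast cell proteases, all had negative values (median -0.75, fry p = 0.00943, adjusted p = 0.283), and 4 of 4 were lower when adjusted over the list alone. With an estimated correlation the list had an adjusted p of 0.594. Mcpt2 was at -0.99 and Tpsab1 at -0.83. The mean list score was dim in every group, below the median of all values (5.83). Without WT_sham replicate 46, which had the highest mast cell score of its group, the median was -0.59 (fry adjusted p = 0.539), and without Het_sham replicate 52 it was -0.47 (fry adjusted p = 0.511), with 0 of the 4 genes lower over the list alone. Without Het_irradiated replicate 29 it was -0.86, and the list passed (fry adjusted p = 0.0258). Gadd45a was higher (0.89) when adjusted over the p53 target list alone, and limma gave it an adjusted p of 0.195 over all genes. All 14 genes of antigen presentation had positive values (median 0.23, fry adjusted p = 0.490), and all 21 fibroblast and matrix genes negative ones (median -0.40, fry adjusted p = 0.482). Without Het_sham replicate 52 the first median was 0.15. The second median was -0.28 without Het_sham replicate 19 and -0.29 without Het_sham replicate 15.

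Host genotypes were compared last, and here the levels come from 2 sets of arrays that, judged by their medians, were treated as normalized separately. In sham-irradiated hosts, Spaca4 had a log2 fold change of -1.05, Tlcd3b of -0.81 and Slc51b, a steroid transporter subunit, of 0.78 (heterozygote minus wild type). Col17a1 was at 2.90 and Krt16 at 1.88, while Tgfb1 was at -1.08 (SE 0.31, limma adjusted p = 0.0218). The dimmer Tgfb1 probe set gave -0.31. The Tgfb1 call ended without WT_sham replicate 46 (-0.81, limma adjusted p = 0.0501) or Het_sham replicate 52 (-0.72, limma adjusted p = 0.12), and those of Col17a1 and Krt16 without any 1 of 7 and of 5 arrays. Without Het_sham replicate 19 Krt16 was at 0.95 (limma adjusted p = 0.243). In irradiated hosts Spaca4 was at -1.25, Hamp2 at -1.12 and Slc51b at 0.84, and the antibody genes Igha and Igkv8-30 were at 1.59 and 2.44. Tgfb1 was at -0.28 there (limma adjusted p = 0.243), against a median of -0.22 over all genes. In the average it was at -0.68 (limma adjusted p = 0.00326). limma called 996 genes in sham-irradiated hosts, 10 higher and 986 lower, 3939 in irradiated hosts, 20 higher and 3919 lower, and 4338 averaged over both, 35 higher and 4303 lower. The median log2 fold change over all genes was -0.23 in that average. After quantile normalization of all arrays together the calls were 44 (24 higher, 20 lower), 234 (100 higher, 134 lower) and 322 (180 higher, 142 lower). On that scale Tgfb1 had a log2 fold change of -0.81 in sham-irradiated hosts (limma adjusted p = 0.370), Slc51b of 1.08 and Spaca4 of -0.74. By fry 6, 5 and 6 gene lists passed in the 3 comparisons, all lower in heterozygote hosts, and 0 in each after quantile normalization or with an estimated correlation. In the average they were the p53 target, oxidative phosphorylation, oxidative stress, immediate early, dendritic cell and Schwann and nerve lists, with medians of -0.22, -0.22, -0.24, -0.25, -0.38 and -0.41 and adjusted p of 0.723, 0.671, 0.535, 0.549, 0.689 and 0.759 with an estimated correlation. Host genotype and normalization set cannot be told apart.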

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

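Values in the sham groups were compared with the rest of their group by the gap to the nearest tumor relative to the group's range, for 55 measures in groups of 9 and 6, 110 comparisons in all. Chance marks about 1 in 20 groups, and 9 were marked. Tests on the pattern of mast cell genes and on that of host genotype, and list values without single tumors, were chosen after the results were seen; the splits of tumors were chosen before.

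WT_sham replicate 46 stood above the other 8 tumors of its group in 4 measures: the mast cell score (8.19, others up to 6.00), the endothelium and pericyte score (11.76, others up to 8.41), the erythrocyte gene Alas2 (12.68, others up to 8.47) and Tgfb1 (11.34, others up to 9.49). WT_sham replicate 60 had a cytotoxic and NK cell score of 7.67 (others up to 6.22), and WT_sham replicate 17 an Ifnz value of 9.05 (others up to 7.90). Het_sham replicate 58 had an oxidative stress score of 10 (others up to 9.37) and a Galnt6 value of 8.96 (others up to 7.15). Het_sham replicate 19 had an 18S control of 9.80, with the others from 11.76 to 12.52.

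Mast cell genes had lower values in tumors of irradiated hosts, with a mean score difference of -0.77 (log2). Much of it rested on WT_sham replicate 46 and Het_sham replicate 52: it was -0.59 and -0.47 without each and -0.29 without both. Those values leave out high scores of the sham groups only. Het_irradiated replicate 29 scored 7.82, near the 8.19 of each of these sham tumors, and pulled the other way: leaving it out alone made the fall larger. Mean scores were 5.31 in sham and 4.60 in irradiated wild-type hosts, and 5.24 and 4.42 in heterozygote hosts. All lay below 5.83, the median of all values. In irradiated hosts the arrays' lower quartiles reached 4.28 in wild-type and 3.99 in heterozygote hosts. The mean signal there was dim, so a fall is hard to measure. Chance among the 30 lists could account for the pattern, at a family-wise p of 0.262 from 100000 permutations. With the 18S control as a covariate the shift was -0.485 (SE 0.287), and without the arrays of low 18S it was -0.775 (SE 0.288). It was -0.02 if WT_sham replicate 46 and Het_sham replicate 52 were left out as well, so the 18S difference and irradiation cannot be told apart. The mean shift of 6 other leukocyte lists was 0.0985 (SE 0.128), which gave no sign of a general fall. It lay above the mast cell shift by 0.866 (SE 0.288) with all tumors and by 0.336 (SE 0.216) without the 2 sham tumors. The second gap is small beside its standard error, so a lower share of all immune cells was not excluded. Loss of mast cells after host irradiation stays open as an untested hypothesis.

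Nearly all genes called between host genotypes were lower in heterozygote hosts, 99.2% of 4338 in the average. With all arrays on one distribution 44.1% of the calls were lower, but that step balances higher and lower values whatever caused the shift, so it does not separate the normalization from a genotype effect. The hybridization controls, which hold no tumor RNA, differed by 0.166 (SE 0.045) on that scale, which a difference between the sets of arrays or the balancing of a shift in tumor RNA would both give. Separate normalization, other differences between the sets and host genotype cannot be told apart, because genotype and set coincide.

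For each comparison 100 splits of the same tumors, the real one included, were drawn. Chance could not be excluded in wild-type hosts, where 36 splits gave as many genes as the real 884 at an unadjusted p under 0.05 (highest other 3101). It could not be excluded in heterozygote hosts either, with 16 splits for 730 genes (highest other 1496). For the difference between genotypes it was 47 splits for 605 genes (highest other 2465). The real number of calls was 0 in these 3 comparisons, which all 100 splits reach by construction, so it decides nothing about chance; the highest others were 511, 40 and 3. For the average over genotypes, 11 splits reached 972 genes (highest other 1835), while 4 splits reached the 1 call (highest other 1). That count was thus uncommon among splits, at 4 of 100, but it is 1 gene and 1 of several counts tested without correction. The call also ended without any 1 of 6 arrays. Chance is therefore excluded neither for that count nor for the number of genes under 0.05. A split in wild-type hosts that called 511 genes against the real 0 points to a structure among the tumors other than irradiation. For host genotype 1 split of 100, the real one, reached 996 calls in sham-irradiated hosts (highest other 749). In irradiated hosts 1 reached 3939 (highest other 180), and in the average 1 reached 4338 (highest other 1071). A random division of the arrays thus did not account for these counts. Host genotype coincides with the sets of arrays treated as normalized separately, however, and a shift between the sets would by itself set the real split apart. The splits therefore decide nothing about an effect of genotype.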

How the results depend on the processing

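Alternatives with the 18S control, and list tests without single arrays, were chosen after the data were seen. Host irradiation gave 0 calls in heterozygote hosts and 0 for the difference between genotypes under every alternative run, and in wild-type hosts under all but 1: with all probe sets there was 1 call. Averaged over genotypes, the 1 call became 15 with all probe sets (4 higher, 11 lower), 19 with array weights (16 higher, 3 lower), and 0 with the 3' minus 5' difference or the 18S control as a covariate; leaving out 1 array gave 0 to 2 calls. There were 2 without WT_sham replicate 31 or 46, WT_irradiated replicate 57, Het_sham replicate 58 or Het_irradiated replicate 26 or 32. Without low 18S arrays there was 1 call, Tmem14c, and not Ankra2. With array weights 5430405H02Rik also passed (-0.37, limma adjusted p = 0.0442). For host genotype in sham-irradiated hosts, the 996 calls became 4032 without a filter, 2128 with all probe sets, 44 with quantile normalization, 172 with only the 2 groups and 604 without low 18S arrays (697 to 1118 without 1 array). In irradiated hosts the 3939 became 8622 without a filter and 234 with quantile normalization (3601 to 4274 without 1 array), and in the average 4338 became 8820 and 322 (3847 to 4579). Gene lists called in wild-type hosts went from 1 to 4 with the preset correlation of camera and to 0 without a filter, with either 18S alternative and without WT_sham replicate 46. The preset correlation gave 13 lists in heterozygote hosts, 8 for the difference and 6 for the average, against 0 by fry and 0 with an estimated correlation. Leaving out 1 array gave 0 to 1 lists in wild-type hosts, 0 in heterozygote hosts, 0 to 1 for the difference (erythrocyte, without WT_sham replicate 3 or 8) and 0 to 1 for the average (mast cell, without Het_irradiated replicate 29). For genotype, the preset correlation gave 12, 18 and 15 lists in sham-irradiated hosts, irradiated hosts and the average, of which 11, 18 and 15 were higher in heterozygote hosts relative to the other genes, where the lists called by fry were lower; the estimated correlation and quantile normalization each gave 0. In sham-irradiated hosts 3 lists were called without low 18S arrays. In irradiated hosts 8 were called with the spike-in covariate, 11 without a filter and 9 with array weights, and in the average 12 without a filter. The causes were not tested, except that all arrays share one distribution after quantile normalization. Ankra2 lost its call without WT_sham replicate 3, 60 or 64 and without Het_sham replicate 19, 38 or 52 (highest adjusted p 0.119). The correlation of irradiation effects stayed between 0.0957 and 0.116. Tgfb1 in the average over genotypes, which was not called, changed sign with the 3' minus 5' difference, the spike-in component or the 18S control as a covariate. It also did so without some single arrays, among them WT_sham replicate 46 (0.12) and Het_sham replicate 19 (0.08). No paired analysis was possible because replicate numbers are not shared between groups. Array signal over background limits dim genes, and 12508 of 18194 named genes passed the filter.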

Other observations

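Of the tests on chromosome 13, the one with the first principal component was chosen before its result was seen, and the others after.

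Tumors of every group differed in programs that irradiation did not separate. The alveolar and milk list, with casein genes, ran from 6.91 to 11.72 (log2, n = 23) in irradiated wild-type hosts and from 8.32 to 11.64 (n = 18) in irradiated heterozygote hosts. Skeletal muscle genes, whose source bulk RNA does not give, ran from 4.80 to 10.96 in irradiated wild-type and from 4.62 to 9.94 in irradiated heterozygote hosts. Proliferation genes had list differences of -0.09 (95% interval -0.40 to 0.22) in wild-type and -0.23 (-0.54 to 0.07) in heterozygote hosts, the latter -0.14 without Het_sham replicate 15. TGF-beta target genes had differences of 0.01 (-0.21 to 0.24) and -0.04 (-0.32 to 0.26).

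Genes of chromosome 13 had higher values in tumors of irradiated hosts of both genotypes, by 0.132 on average. Chance among 20 chromosomes was argued against by a family-wise p of 0.00793 from permutations within host genotype. The 18S control, which differed in wild-type hosts, was argued against by a shift of 0.1283 with it as a covariate (SE 0.037, 0.12 in wild-type hosts). The median over chromosome 13 genes was 0.136, above 100% of 10000 gene sets matched on expression, whose own median was -0.002. Expression level alone thus did not account for the shift. Those sets say nothing about chance, since the chromosome was picked for its values. With the first principal component as a covariate the shift was 0.1232 (SE 0.033), but that component did not differ detectably between the groups, so cell makeup stays open. The shift was positive in 100% of 24 windows of 5 Mb in both genotypes, which is consistent with a change along the whole chromosome. A candidate explanation is that tumors arising in irradiated hosts more often carried extra copies of chromosome 13. The score is centred within host genotype, so fewer copies in tumors of sham-irradiated hosts would give the same difference. Both are hypotheses found and tested on the same data, and DNA copy number was not analysed here. Leaving out 1 tumor kept the mean shift between 0.115 and 0.151. The lowest shift came without WT_sham replicate 46, which had the lowest score of all tumors (-0.36). The exact permutation p in wild-type hosts was then 0.0118. In heterozygote hosts the exact permutation p rose to 0.103 without Het_sham replicate 38 and to 0.0659 without replicate 52. The family-wise p was computed with all tumors.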
